A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

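The data are RNA-seq counts per gene from 12 cultures of Escherichia coli K-12 MG1655, a laboratory strain, in 4 groups of 3 biological replicates. Wild type (WT) and a strain deleted for clpP, the proteolytic subunit of the ClpXP and ClpAP proteases, were each sampled 10 min after addition of 250 µM DPTA, a donor of nitric oxide (NO), or of its solvent alone, called untreated here. Per the labels' protocols, cells grew in MOPS minimal medium with 10 mM glucose at 37 °C and entered a stirred aerobic bioreactor at an OD600 of 0.05. RNA was stabilised at once, purified for all samples together, depleted of rRNA and made into strand-specific libraries, which were sequenced as 1 pool in 1 lane with single-end reads of 67 nt, per the labels' protocols.

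The submitters' processing notes name TopHat2 2.0.9, HTSeq 0.6.0, R 3.1.0 and DESeq2 1.4.5. The genome build, the annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. The authors deposited raw counts per gene for each library, whole numbers that had not been normalized, and a table of the whole series with the same counts. All 12 count columns of that table were equal to the separate files. The authors' deposited table also gives log2 fold changes, p-values and adjusted p-values for 4 comparisons, which are cited only where named. The files list 4497 genes by symbol, of which 4204 matched the ASM584v2 annotation by symbol and 227 by an older name. That annotation was used only for names and for which genes are neighbours.

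Library totals ran from 4725868 to 8560927 counts. Genes of rRNA took 0.0102% to 0.461% of a library and genes of tRNA at most 0.0667%. No entry without a gene name was present. Chi-square statistics of the counts of replicate pairs ran from 19.1 to 48.9 per degree of freedom, so no pair was alike within sampling noise and each library counts once.

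Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at a minimum count of 10, which left 3785 genes and removed 712. Libraries were scaled with TMM factors, which ran from 0.896 to 1.128. A quasi-likelihood model with 4 group means was fitted to all 12 libraries, which leaves 8 residual degrees of freedom, and had a biological coefficient of variation of 21.8%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 in the F test. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries. The interaction is the log2 response to DPTA in the deletion minus that in WT.

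The groups, the tests, the 31 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists hold 538 genes, all found in the files, of which 523 were tested. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The named genes are clpP, tig, clpX and lon; hmp, norV, ytfE and hcp; up to 10 genes with the largest rise and 10 with the largest fall per pairwise comparison among called genes whose replicates do not overlap and whose mean is at least 50 counts, without rRNA and tRNA genes and clpP; 8 per direction for the interaction; and up to 4 members with the smallest adjusted p of each list described. For 3 counts or fewer summed over a group a ratio is given with its exact 95% counting interval, which covers counting error only.

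The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library totals alone, upper-quartile factors, no filter, removal of rRNA and tRNA genes, the replicate number as a block, a fold of at least 2, each library left out in turn, and a fit of the 6 libraries compared. Removal of fliC, hmp, norV, norW and ytfE before scaling was added after the data had been seen. Other splits of the libraries were fitted in the same way, 10 for each pairwise comparison and 100 for the interaction.

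The test was tried on simulated counts in which all libraries shared the same mean profile. In a single group 67, 67 and 66 genes were changed by folds of 1.5, 2 and 4. For the simulated DPTA response in WT, tested on 3713 genes, 47.8% of the genes changed by a fold of 2 and 77.3% of those changed by a fold of 4 were called, and 5% of calls were false. For the simulated response in the deletion (3720 genes) the values were 61.2%, 78.8% and 9.3%. For the simulated deletion effect they were 38.8%, 84.8% and 5.9% untreated (3733 genes) and 61.2%, 86.4% and 9.5% with DPTA (3713 genes). For the simulated interaction (3716 genes) they were 32.8%, 65.2% and 5.7%. There 1.5% of the genes changed by a fold of 1.5 were called, so small interactions were mostly missed in the simulation. In the simulated pairwise comparisons 17.9% to 23.9% of the genes changed by that fold were called. Most small changes were therefore missed there too, and an uncalled gene may still have changed. In the real data far more genes changed, with 64% called for DPTA in WT, and library composition differed between groups. The simulated shares therefore need not hold for the real comparisons.

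Of 76 genes named by a part of the rule other than list membership, some of which are also in a list, 73 matched the annotation by symbol and 27 of those overlap a neighbour there, among them norV with norW, fliF with fliG and rnpA with yidD. How the counting assigned reads in such overlaps is not given, so these values are uncertain, as are those of similar copies such as tar, tsr, tap and trg, or ibpA and ibpB.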

Results

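Gene expression was measured by RNA-seq in E. coli MG1655 and in its clpP deletion strain, with and without the NO donor DPTA, in 3 cultures for each of the 4 groups. The series title names ClpP as a regulator of transcript levels in cells under NO stress. Library totals were 5592324, 4885380 and 4725868 counts in untreated WT and 7219740, 6425005 and 7152507 in WT with DPTA. In the deletion they were 7877897, 5547703 and 8560927 untreated and 6940676, 7527094 and 5986821 with DPTA. The flagellin gene fliC alone took 4.84% ± 0.412, 9.6% ± 0.58, 11.7% ± 0.372 and 19.1% ± 0.368 of the counts in these groups. In a principal component analysis, component 1 held 71.8% of the variance and parted the treatments, and component 2, with 7.2%, parted the strains. Replicate 3 of the deletion with DPTA stood apart on component 3, with 4% of the variance, at 30.71 beside -19.57 and -18.48 for its replicates, and lay at -28.26 on component 2 beside -16.2 and -15.36. Without it 1145 genes were higher and 1255 lower for DPTA in the deletion, 431 and 369 for the deletion against WT with DPTA, and 107 and 134 for the interaction.

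The deleted gene was examined first. clpP had 3440, 2931 and 3178 counts in the untreated WT libraries and 8092, 5964 and 7503 in those with DPTA. The deletion libraries held 100, 70 and 109 counts untreated and 218, 149 and 137 with DPTA. clpP was thus lower by -5.50 ± 0.16 (log2, SE; adjusted p = 5.12e-12) untreated and by -5.13 ± 0.16 (adjusted p = 8.73e-12) with DPTA. Each library matched its label. clpX, the neighbour that encodes the ATPase partner of ClpP, was lower in the deletion by -1.69 ± 0.11 (adjusted p = 1.01e-07) untreated and -1.0 ± 0.11 (adjusted p = 1.53e-05) with DPTA. On its far side lon, another protease gene, was higher by 0.47 ± 0.09 (adjusted p = 0.00365) untreated and lower by -0.37 ± 0.09 (adjusted p = 0.00743) with DPTA. The upstream neighbour tig, a ribosome-bound chaperone gene, had values of -0.47 ± 0.19 (adjusted p = 0.175) and 0.49 ± 0.19 (adjusted p = 0.0757).

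The first comparison asked what the NO donor does in WT. The largest rises were in norV, norW and ytfE. norV, the flavorubredoxin that reduces NO, went from 17.9 ± 4.29 to 34900 ± 1360 CPM (SD, n = 3), a log2 change of 10.92 ± 0.20 (adjusted p = 1.15e-15). Its partner gene norW rose by 10.60 ± 0.16 and ytfE, which acts in repair of iron centres, by 10.51 ± 0.19. The flavohemoglobin gene hmp rose by 8.08 ± 0.16 (adjusted p = 2.28e-15) and the hybrid cluster protein gene hcp by 6.90 ± 0.17 (adjusted p = 3.28e-14). The other genes among the 10 largest rises by the rule for named genes were adiY (8.42), adiC (7.67), alaE (8.26), yohJ (7.04) and yohK (5.90). Across the genome 1225 genes rose and 1197 fell, 64% of those tested, and 866 and 890 of them by a fold of at least 2.

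**Figure D1:**
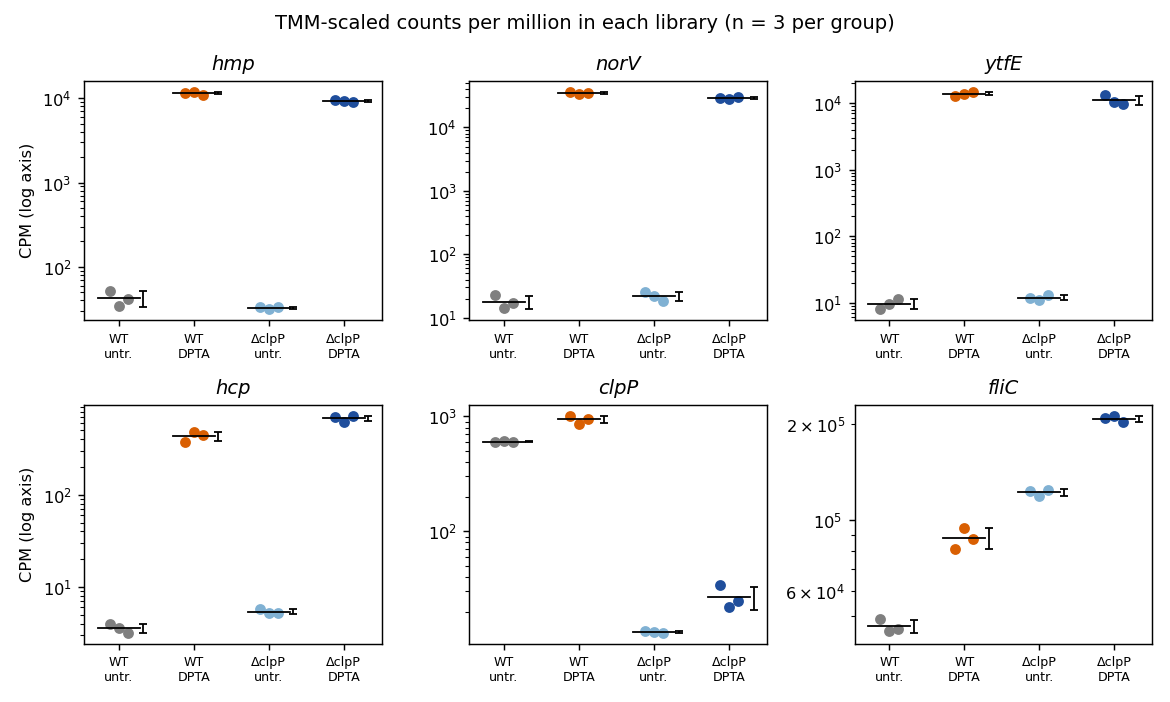
TMM-scaled CPM (log axes) of 6 genes in the 12 libraries, with 1 point per library, a line at the group mean and a bar for its SD (n = 3). hmp, norV, ytfE and hcp lie far higher with DPTA in both strains, clpP is low in the 6 deletion libraries, and fliC is higher in the deletion under both treatments.

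Of the gene lists 9 were called higher in WT. All 10 measured genes of the NsrR regulon, which a NO-sensing repressor controls, rose (median log2 4.94; camera adjusted p = 1.32e-21, and adjusted p = 0.000569 with an estimated correlation). All 3 NorR genes rose (median 10.60; adjusted p = 3.1e-14, and adjusted p = 0.00453 with an estimated correlation). All 6 genes of Suf, an iron-sulfur cluster assembly system used under stress, rose between 3.47 and 3.81 (adjusted p = 1.19e-09, and adjusted p = 0.0283 with an estimated correlation). Among genes of the cytochrome bd oxidases 4 of 7 rose, led by cydA (4.51 ± 0.10) and cydB (4.22 ± 0.11), and cydD fell (-0.45 ± 0.14, adjusted p = 0.0122; adjusted p = 0.0562 without WT DPTA replicate 2). The oxidase list was called higher (adjusted p = 0.000122, and adjusted p = 0.0198 with an estimated correlation). Of 22 toxin-antitoxin genes 18 rose, among them dinJ (2.85 ± 0.17) and mqsA (2.72 ± 0.18), with adjusted p = 0.000126, and adjusted p = 0.0188 with an estimated correlation.

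A further 4 lists were called higher in WT with the preset correlation and lost the call with an estimated one. Iron acquisition genes repressed by Fur had 23 of 42 members higher and 8 lower, with feoB at 3.73 ± 0.12 and fes at 2.45 ± 0.11 (adjusted p = 0.00104; adjusted p = 0.389 with an estimated correlation). The OxyR list had 8 of 11 higher and 1 lower, with grxA at 3.52 ± 0.23 and ahpF at 2.78 ± 0.14 (adjusted p = 0.0128; adjusted p = 0.239 with an estimated correlation). The SOS list of DNA damage genes had 16 of 29 higher and 3 lower, with sulA at 2.11 ± 0.17 and lexA at 1.83 ± 0.10 (adjusted p = 0.0192; adjusted p = 0.239 with an estimated correlation). General stress genes that depend on sigma S had 17 of 30 higher and 3 lower, with dps at 3.39 ± 0.27 and rpoS itself at 1.48 ± 0.14 (adjusted p = 0.0165; adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, the counts of the 9 lists called higher were the same except for Fur, with 10 lower, OxyR, with 9 higher and 2 lower, and toxin-antitoxin genes, with 19 higher.

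Of the gene lists 8 were called lower in WT. All 15 measured methionine genes fell (median -4.75; adjusted p = 1.43e-21, and adjusted p = 0.019 with an estimated correlation). metF went from 950 ± 49.8 to 3.95 ± 2.6 CPM, and metA from 5960 ± 1410 to 28.4 ± 8.16. All 14 purine genes fell (median -3.43; adjusted p = 1.61e-12; adjusted p = 0.117 with an estimated correlation), among them purE (-6.10 ± 0.39) and purM (-5.64 ± 0.35). Of 54 ribosomal protein genes 49 fell and 1 rose (median -1.68; adjusted p = 2.96e-14; adjusted p = 0.331 with an estimated correlation), with rpsT at -4.27 ± 0.15. All 8 histidine genes fell (median -1.05; adjusted p = 0.0134; adjusted p = 0.437 with an estimated correlation), as did 7 of 10 pyrimidine genes (median -1.13; adjusted p = 0.0262; adjusted p = 0.471 with an estimated correlation). Of 22 genes for aerobic respiration 13 fell and 2 rose, with cyoA at -4.87 ± 0.24 (adjusted p = 0.00263; adjusted p = 0.533 with an estimated correlation). The TCA cycle list had 12 of 16 lower and 1 higher, with sdhC at -5.35 ± 0.36 (adjusted p = 0.00413; adjusted p = 0.437 with an estimated correlation).

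Flagellar and chemotaxis genes went both ways in WT, with 33 of 50 lower and 10 higher (median -0.74; adjusted p = 0.00533; adjusted p = 0.437 with an estimated correlation). fliI fell by 2.62 on the log2 scale, while flgM, the inhibitor of the flagellar sigma factor, rose by 2.36 ± 0.11. The largest fall of the list was that of flhD (-4.72 ± 0.45), with flhC at -3.53 ± 0.34. These 2 genes of the flagellar master regulator were named after their values were seen. In the deletion they changed by -3.35 and -2.45 with DPTA. Other large falls in WT were those of metR (-6.47), metB (-6.39), metN (-5.71), rnpA (-6.10), mglA (-6.29) and yidD (-6.45). With DPTA the means of rnpA, mglA and yidD were 2.94, 0.259 and 0.256 CPM. Adjusted over the list alone, the 8 lists called lower had the same counts except for ribosomal proteins (51 lower) and flagella (34 lower).

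The same comparison in the deletion gave a similar number of genes. There 1172 rose and 1273 fell, 64.6% of those tested, and 823 and 960 of them by a fold of at least 2. norV rose by 10.38 ± 0.19, norW by 10.07 ± 0.16, ytfE by 9.87 ± 0.18, hmp by 8.14 ± 0.16 and hcp by 6.96 ± 0.16, with adjusted p between 3.48e-16 and 2.12e-14. alaE, which had 2 counts over the 3 untreated deletion libraries, was higher with DPTA by a ratio of 2650 (95% counting interval 734 to 21900). ydiY, with 1 count over the deletion libraries with DPTA, was lower there, with a ratio of untreated to DPTA of 599 (95% counting interval 107 to 23700). By the rule for named genes, other large rises were adiY (8.34), yohJ (7.32), yohK (6.09) and yhaK (5.90). Other large falls by that rule were rnpA (-8.22), yliE (-6.43), yidD (-6.27), mepS (-6.00) and yejG (-5.88).

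In the deletion the NsrR (10 of 10 higher), NorR (3 of 3), Suf (6 of 6), cytochrome bd (4 of 7 higher, 1 lower) and toxin-antitoxin (16 of 22) lists were again called higher, with adjusted p of 3.82e-21, 7.52e-14, 2.07e-09, 0.000215 and 9.61e-06. With an estimated correlation their adjusted p were 0.00104, 0.00757, 0.0249, 0.0249 and 0.0169. Fur (23 of 42 higher, 9 lower), OxyR (8 of 11, 1 lower), SOS (17 of 29, 5 lower) and sigma S genes (16 of 30, 4 lower) had adjusted p of 0.00618, 0.00282, 0.0077 and 0.00991, and adjusted p of 0.475, 0.163, 0.163 and 0.651 with an estimated correlation. All 15 methionine genes fell (median -4.06; adjusted p = 1.6e-15, and adjusted p = 0.0249 with an estimated correlation). All 14 purine genes fell (median -2.20; adjusted p = 1.52e-07; adjusted p = 0.163 with an estimated correlation). Of ribosomal protein genes 41 of 54 fell and 2 rose (adjusted p = 5.21e-09; adjusted p = 0.475 with an estimated correlation), and of flagellar genes 37 of 50 fell and 6 rose (adjusted p = 7.05e-05; adjusted p = 0.345 with an estimated correlation). Heat shock genes had 15 of 20 lower and 3 higher (median -1.57; adjusted p = 0.00187; adjusted p = 0.525 with an estimated correlation), with groS at -3.36 ± 0.17 and groL, the chaperonin, at -2.97 ± 0.11. Adjusted over the list alone, these counts were the same except for sigma S genes, with 17 higher.

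The responses of the strains overlapped. Of the genes called higher 1001 were shared, against 379.3 for independent lists, and of those called lower 1059, against 402.6. Across genes, which are not independent replicates, log2 changes had Pearson's r = 0.884 and Spearman's rho = 0.89, and 12 genes were called in opposite directions. The comparisons share no library.

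**Figure D2:**
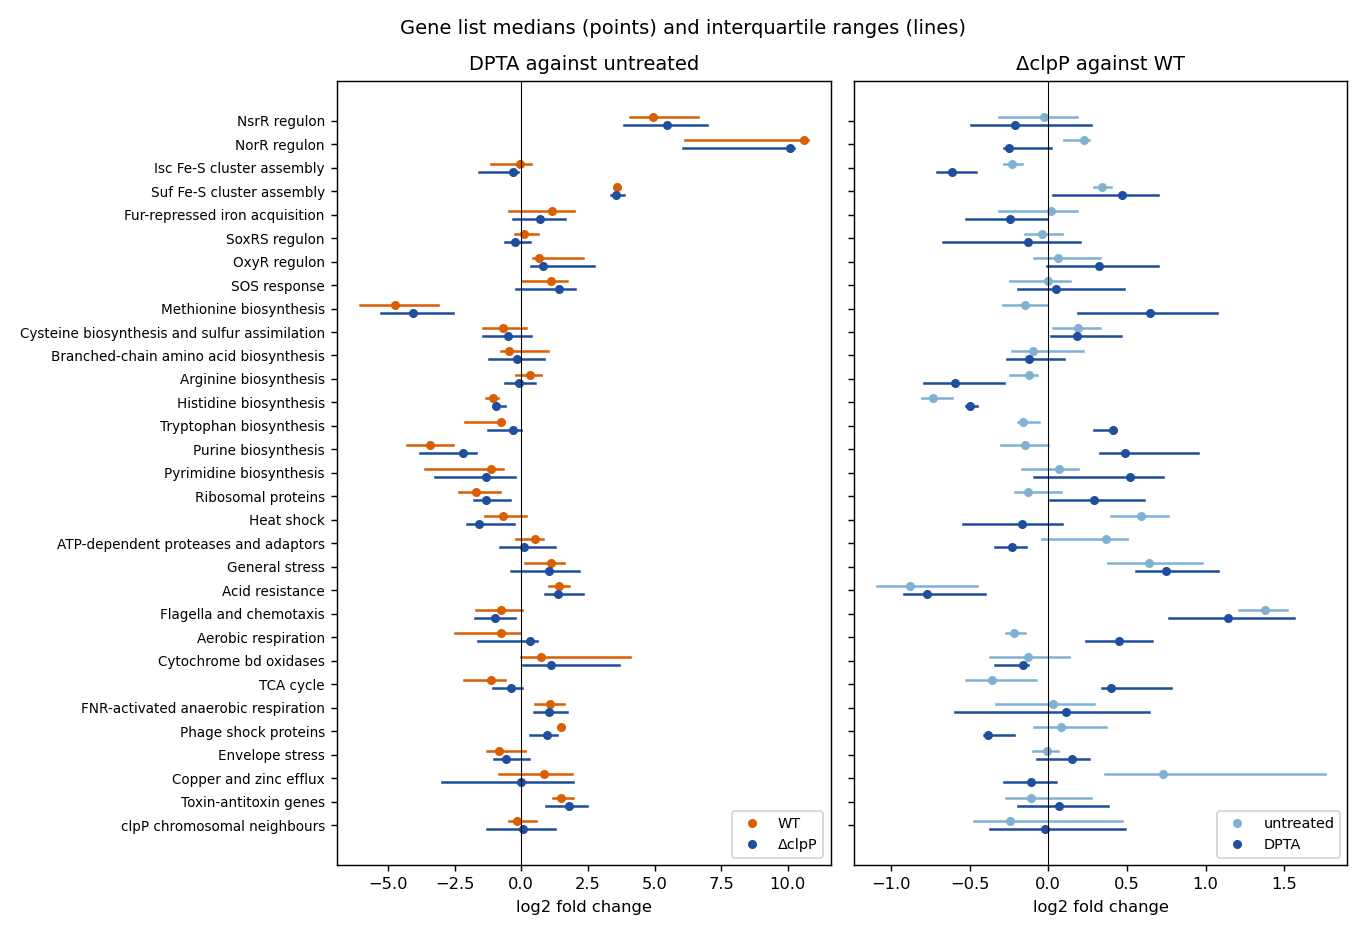
Median log2 fold change (points) and interquartile range (lines) of each of the 31 gene lists, for DPTA against untreated in both strains (left) and for the deletion against WT under both treatments (right). NsrR, NorR and Suf lie right of 0 and methionine and purine genes left of 0 in both strains, while flagellar genes have medians of 1.38 and 1.14 in the deletion.

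The next comparison asked how the deletion strain differs from WT in untreated cells. No complemented or second deletion strain was measured, so other differences between the strains cannot be told apart from loss of ClpP. Flagellar and chemotaxis genes were higher in the deletion: 46 of 50 passed the test and none was called lower (median 1.38; camera adjusted p = 1.91e-145, and adjusted p = 9.9e-05 with an estimated correlation). fliC went from 46300 to 122000 CPM (1.4 ± 0.08, adjusted p = 4.01e-08), and motA, of the flagellar motor, was higher by 1.57 ± 0.11. Also among the largest rises by the rule for named genes were flhE (2.26), fliS (1.95), fliT (1.79), flgD (1.77) and the chemoreceptor gene trg (1.83), with ymdA (2.43), yecR (2.01) and ymfJ (1.86). Heat shock genes had 12 of 20 members higher and 1 lower, clpX (median 0.59; adjusted p = 9.73e-07; adjusted p = 0.667 with an estimated correlation). The small heat shock genes ibpA and ibpB were higher by 1.80 ± 0.17 and 2.27 ± 0.45, groL by 0.75 ± 0.11 and dnaJ by 0.79 ± 0.13. Sigma S genes had 9 of 30 higher, such as ydcS (1.33 ± 0.22) and amyA (1.26 ± 0.14), and 1 lower, rpoS itself at -0.53 (adjusted p = 0.0386), which was named after its value was seen. That list was called higher (median 0.64; adjusted p = 6.57e-08; adjusted p = 0.667 with an estimated correlation).

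Lower in the untreated deletion were the histidine genes, 8 of 8 (median -0.73; adjusted p = 2.06e-10; adjusted p = 0.258 with an estimated correlation), with hisG at -0.85 ± 0.12. The largest falls by the rule for named genes were those of csgG (-2.14 ± 0.37), pfkB (-1.83 ± 0.21), clpX (-1.69 ± 0.11), yahA (-1.63), glnK (-1.53), cybB (-1.49), amtB (-1.41), the fimbrial gene fimA (-1.27 ± 0.16), yceI (-0.94) and gltF (-0.91). Acid resistance (median -0.88, 1 of 12 lower), aerobic respiration (median -0.22, 0 of 22) and TCA cycle genes (median -0.36, 1 of 16) were called lower as lists at adjusted p = 0.0255 each, with few single members past the test, and at adjusted p of 0.667, 0.825 and 0.825 with an estimated correlation. Adjusted over the list alone, 48 flagellar, 14 heat shock and 14 sigma S genes were higher, and the other counts of the called lists were the same. hmp, norV, ytfE and hcp had log2 values of -0.38, 0.29, 0.32 and 0.59, with adjusted p of 0.0921, 0.346, 0.309 and 0.103.

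In all 171 genes were higher and 65 lower in the untreated deletion, and 91 and 11 by a fold of at least 2. The split depended on the scaling: it was 150 and 115 with DESeq2 size factors in edgeR, 117 and 169 with library totals, 151 and 99 with upper-quartile factors, and 151 and 98 without 5 abundant changing genes. DESeq2, which differs also in its test and tested 2841 genes, gave 196 and 210. Without WT untreated replicate 2, 111 genes were higher, and without untreated deletion replicate 1, 34 were lower. The list calls were lost for acid resistance without WT untreated replicate 3 (adjusted p = 0.222), without untreated deletion replicate 2 (0.0713) or with library totals (0.06), for aerobic respiration without WT untreated replicate 2 (0.299), and for the TCA cycle without that library (0.0758) or untreated deletion replicate 2 (0.0576). Among the genes named by the rule in this comparison, those that lost their call without 1 library were glnK, gltF, hdeA and icd. For glnK this was without WT untreated replicate 2 or untreated deletion replicate 1 (highest adjusted p = 0.0834). For gltF it was without WT untreated replicate 2 (0.054). For hdeA it was without WT untreated replicate 3 or untreated deletion replicate 2 (highest 0.111), and for icd without untreated deletion replicate 1 (0.0525). The call of rpoS, which the rule did not name here, was not followed in these fits.

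Under DPTA the deletion differed from WT in more genes, 489 higher and 413 lower, and 165 and 108 by a fold of at least 2. Flagellar genes were again higher, 45 of 50 with none called lower (median 1.14; adjusted p = 1.52e-55, and adjusted p = 0.00389 with an estimated correlation). flgB was higher by 2.34 ± 0.12, flgC by 2.15 ± 0.14, flgA by 2.09 ± 0.15 and fliF by 2.02 ± 0.17, and fliC went from 87800 to 208000 CPM. Other large rises were yecR (2.41), the lipocalin gene blc (2.34), ybhN (2.09), fliJ (2.07), fic (1.97) and fliG (1.95). Sigma S genes had 17 of 30 higher, among them wrbA (1.60 ± 0.26) and yeaG (1.38 ± 0.24), while rpoS was lower (-0.92 ± 0.14, adjusted p = 0.000343). That list had a median of 0.75 (adjusted p = 5.96e-07; adjusted p = 0.615 with an estimated correlation).

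The methionine, purine, ribosomal protein, aerobic respiration and TCA cycle lists were also called higher in the deletion under DPTA, each with the preset correlation and not with an estimated one. Methionine genes had 10 of 15 higher, with metJ at 1.43 ± 0.19 and metK at 1.20 ± 0.15, and purine genes 6 of 14 higher and 1 lower, with purD at 1.81 ± 0.19 (adjusted p = 4e-04 each). Aerobic respiration had 10 of 22 higher, with cyoB at 1.41 ± 0.21 (adjusted p = 4e-04), TCA cycle 7 of 16, with sdhA at 1.38 ± 0.24 (adjusted p = 0.00137), and ribosomal proteins 19 of 54 higher and 2 lower, with rplB at 1.00 ± 0.18 (adjusted p = 0.00199). With an estimated correlation these lists had adjusted p of 0.615, or 0.719 for ribosomal proteins. Without DPTA deletion replicate 2 the ribosomal list had adjusted p = 0.0763.

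Lower under DPTA were genes of Isc, the housekeeping iron-sulfur assembly system, 6 of 8 (median -0.61; adjusted p = 0.000459; adjusted p = 0.546 with an estimated correlation), with iscR at -0.90 ± 0.13. Histidine genes had 7 of 8 lower (median -0.50; adjusted p = 0.00199; adjusted p = 0.615 with an estimated correlation), of which hisB and hisH lost their call without WT DPTA replicate 1 (adjusted p = 0.0597 and 0.0677). Fur genes had 9 of 42 lower and 3 higher (adjusted p = 0.0468; adjusted p = 0.615 with an estimated correlation), a list call that was lost without WT DPTA replicate 1 (0.0884) or 2 (0.0603), without DPTA deletion replicate 2 (0.0685) or 3 (0.149), with DESeq2 size factors in edgeR (0.0519) or without 5 abundant genes (0.0526). The largest falls by the rule for named genes were fimD (-3.55 ± 0.53), fimC (-2.77 ± 0.43), evgA (-2.31), yjhY (-2.08) and bhsA (-1.79). They were followed by mltC (-1.76), yddA (-1.65), ydeH (-1.63), cspA (-1.60) and fimI (-1.57). ydeH had adjusted p = 0.0484, which reached 0.119 with single libraries left out and passed 0.05 without any of WT DPTA replicates 1, 2 and 3 and deletion DPTA replicates 1 and 2. Adjusted over the list alone, 47 flagellar, 24 sigma S, 13 aerobic respiration, 8 TCA and 7 purine genes were higher. By that adjustment 8 histidine genes and 1 methionine gene were lower, and the other counts of the called lists were the same.

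Of the NO detoxification genes, hcp was higher in the deletion under DPTA (0.64 ± 0.12, adjusted p = 0.00101), while hmp, norV and ytfE had values of -0.31, -0.25 and -0.32 (adjusted p = 0.0591, 0.176 and 0.0703). Of the 10 NsrR genes 2 were called higher and 1 lower (3 lower when adjusted over the list alone), and of the 3 NorR genes 1 was called lower. Neither list was called by camera (adjusted p = 0.638 and 0.673). With library totals the split under DPTA was 273 higher and 872 lower, and with upper-quartile factors 400 and 541. Library totals moved the median of all genes from -0.03 to -0.29 in this comparison and that of the flagellar genes from 1.14 to 0.88. The deletion effects under the 2 treatments shared 104 genes called higher, against 22.1 for independent lists, and 32 called lower, against 7.1, with 11 in opposite directions. The shared lower genes numbered 17 without WT DPTA replicate 1, 53 with DESeq2 size factors in edgeR and 81 with DESeq2. Across genes r was 0.27 and rho 0.25, and no library is shared.

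The interaction tested whether the response to DPTA differed between the strains. The methionine, purine, TCA and aerobic respiration lists were called toward a positive interaction and the heat shock list toward a negative one, with the preset correlation. With an estimated correlation these 5 lists had adjusted p of 0.436, or 0.511 for aerobic respiration. The methionine median with DPTA was -4.75 in WT and -4.06 in the deletion, that of purine genes -3.43 and -2.20, and that of heat shock genes -0.67 and -1.57. For aerobic respiration it was -0.75 and 0.33, with 11 genes higher and 9 lower in the deletion. Of 15 methionine genes 7 had a positive interaction (median 0.73; camera adjusted p = 3.33e-08), with metK at 1.5 ± 0.21. So had 5 of 14 purine genes (median 0.74; adjusted p = 3.84e-08), with purD at 1.89 ± 0.26, 8 of 16 TCA genes (median 0.77; adjusted p = 5.88e-09), with sdhA at 1.90 ± 0.34, and 8 of 22 aerobic respiration genes (median 0.56; adjusted p = 1e-09), with cyoB at 1.70 ± 0.29. Heat shock genes had 11 of 20 negative and 1 positive (median -0.80; adjusted p = 4.13e-09). groL illustrates this, with 7610 and 12800 CPM in untreated WT and deletion and 2370 and 1630 CPM with DPTA (interaction -1.29 ± 0.15, adjusted p = 0.000689).

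Ribosomal proteins (5 of 54 positive, 1 negative, adjusted p = 7.01e-06), tryptophan genes (1 of 5 positive, adjusted p = 0.0409), flagella (12 of 50 negative, 2 positive, adjusted p = 0.011) and ATP-dependent proteases (4 of 11 negative, 1 positive, adjusted p = 0.0359) were also called, with adjusted p of 0.674, 0.58, 0.63 and 0.63 with an estimated correlation. The flagellar call was lost without WT untreated replicate 3 (0.0698) or WT DPTA replicate 2 (0.206). The protease call was lost without WT untreated replicate 2 (0.106), WT DPTA replicate 3 (0.125), untreated deletion replicate 2 (0.0728), DPTA deletion replicates 2 (0.0674) and 3 (0.0964), with DESeq2 size factors in edgeR (0.0785) or without 5 abundant genes (0.0621). The tryptophan call was lost without WT untreated replicate 1 (0.0622), WT DPTA replicates 1 (0.05) and 3 (0.0991), untreated deletion replicate 2 (0.0728), or DPTA deletion replicates 2 (0.124) and 3 (0.0627). It was also lost with library totals (0.0596) or with the replicate number as a block (0.0505). Adjusted over the list alone, 10 methionine, 10 purine, 10 TCA, 12 aerobic respiration, 9 ribosomal, 2 tryptophan and 5 flagellar genes were positive. By that adjustment 12 heat shock, 18 flagellar, 5 protease genes and 1 purine gene were negative, and the other counts of the called lists were the same. Of the 3 NorR genes, a list that was not called, 2 were then negative. hmp, norV, ytfE and hcp had interactions of 0.07, -0.54, -0.64 and 0.05, with adjusted p of 0.866, 0.11, 0.0691 and 0.932.

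In all 135 genes had a positive and 147 a negative interaction, and 69 and 63 by a fold of at least 2. The split was 180 and 101 with DESeq2 size factors in edgeR, 88 and 220 with library totals, 177 and 113 without 5 abundant genes and 304 and 181 with DESeq2. Positive interactions numbered 89, 78, 81 and 87 without WT untreated replicate 1, WT DPTA replicate 1, untreated deletion replicate 1 and DPTA deletion replicate 2. Negative ones numbered 84 and 97 without WT untreated replicates 1 and 2, 78 without WT DPTA replicate 1, and 66, 86 and 84 without untreated deletion replicates 1, 2 and 3.

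**Figure D3:**
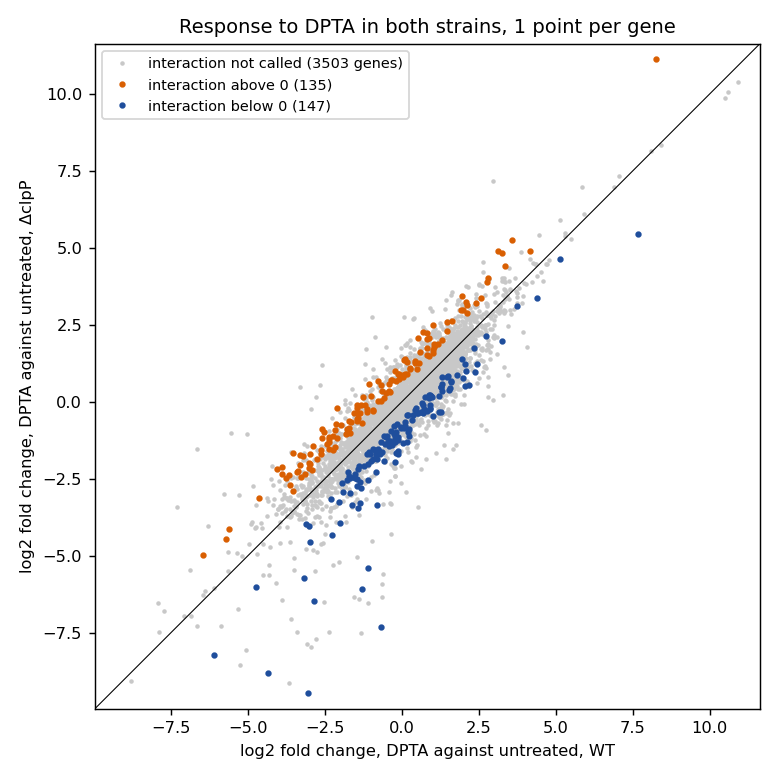
Log2 fold change with DPTA in WT (x axis) and in the deletion (y axis), 1 point per gene over 3785 genes, with the line of equal response. Most genes lie near the line (r = 0.884), and the 135 genes with a positive and 147 with a negative interaction lie on its 2 sides.

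In WT with DPTA 14 lists were not called by camera. Their medians were -0.05 for Isc, 0.12 for SoxRS, -0.68 for cysteine, 0.33 for arginine, -0.75 for tryptophan, -0.67 for heat shock, 0.52 for ATP-dependent proteases, 1.4 for acid resistance, 1.09 for FNR-activated anaerobic respiration, 1.51 for phage shock, -0.83 for envelope stress, 0.85 for copper and zinc efflux and -0.16 for the clpP neighbours. The adjusted p were 0.592, 0.438, 0.108, 0.752, 0.0567, 0.215, 0.415, 0.104, 0.0754, 0.109, 0.261, 0.171 and 0.796 in that order. Branched-chain amino acid genes had a median of -0.46 with a mean of 0.10 and a test direction upward (adjusted p = 0.739), from 6 genes higher and 8 lower. In the deletion with DPTA, SoxRS genes had a median of -0.24 with a mean of 0.11, and aerobic respiration a median of 0.33 with a mean of -0.62 and a test direction downward (adjusted p = 0.646 and 0.385). SoxRS, cysteine, branched-chain, arginine, anaerobic respiration, phage shock, envelope stress, copper and zinc efflux and clpP neighbour lists were not called in any of the 5 comparisons.

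The authors' deposited table gives 1107 genes higher and 1298 lower for DPTA in WT, 1118 and 1303 for DPTA in the deletion, 225 and 163 for the untreated deletion and 496 and 337 for the deletion with DPTA. Its calls shared 2280, 2342, 230 and 752 genes with those given here, 0 of them in the opposite direction. Log2 changes in the authors' deposited table and here had r across genes of 0.997, 0.992, 0.963 and 0.87.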

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

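The tests of technical and biological explanations here were chosen only after the results were seen, except for the other splits of the libraries.

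By the test of the difference between the strains in their response to DPTA, 44 named genes were called, and 9 gene lists with a preset correlation. Some of these lists share members and are not separate evidence. The genes sdhA, sdhB, sdhC and sdhD are in both the TCA cycle and aerobic respiration lists. The genes clpX, clpB, lon, hslU, hslV and ftsH are in both the heat shock and ATP-dependent protease lists. None of the 9 lists was called with an estimated correlation (adjusted p from 0.436 to 0.674). List medians of the interaction (log2) were 0.73 for methionine, 0.74 for purine, 0.77 for TCA cycle, 0.56 for aerobic respiration, 0.48 for tryptophan and 0.38 for ribosomal protein genes, and -0.80 for heat shock, -0.32 for ATP-dependent proteases and -0.27 for flagella. Positive values in these groups were metK 1.5, metJ 1.28, metN 1.24 and metQ 0.73, purD 1.89, purT 1.54, purL 1.44 and purB 1.25, sdhA 1.90, sdhB 1.65, cyoB 1.70, fumA 1.54, icd 0.98, nuoC 0.87 and trpB 0.68, and rplB 1.21, rplA 1.09, rplD 1.04 and rplF 0.77. Negative values were groS -1.75, groL -1.29, htpG -1.24, lon -0.84, hslV -0.86 and hslU -0.70, and motA -1.19, fliT -1.11, motB -1.09 and flgK -1.04. The clpP neighbours clpX and tig had 0.69 and 0.96. Outside the lists lldP had 1.88, uspB 1.79, uraA 1.78 and ychH 1.66, and bioD had -2.55, fimD -2.55, adiC -2.22, rnpA -2.12, yciA -2.06, cspA -2.03 and mltC -1.95. The values of alaE (2.86) and ydiY (-4.46) depend on the prior count of the model, since alaE had 2 counts over the untreated deletion libraries and ydiY 1 over those with DPTA.

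Several of these calls depended on single libraries. Of 12 fits with 1 library left out, the call was lost in 11 for trpB (highest adjusted p = 0.117), 10 for yciA (0.11), 9 for alaE (0.131), fimD (0.0754), hslU (0.112), rnpA (0.105) and uraA (0.0882), 8 for rplF (0.0743) and tig (0.102), 7 for metQ (0.0868) and ychH (0.0954) and 6 for adiC (0.204). For rplD it was lost without WT DPTA replicate 1 or DPTA deletion replicate 2 (0.0505). Of 139 further genes named only in pairwise comparisons, 29 passed the interaction test, 15 positive and 14 negative, from -1.44 to 1.59.

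The first pattern is that clpP reads remained in the deletion libraries, at 2.18% to 3.59% of the WT level, and that clpX was lower there. Reads given to the wrong library of the pool are argued against by norV, which reached at most 0.079% of its DPTA level in an untreated library. Lower expression of heat shock genes as a whole is argued against in untreated cells by their median without clpX, 0.62. With DPTA the median of the whole list, -0.17, was far smaller than the change of clpX, -1.0. That list includes clpX, and 6 of its genes were lower and 2 higher, so a contribution stays open there. A local effect of the deletion on the clpP-clpX transcript may account for clpX. The next gene, lon, was higher by 0.47 untreated and with DPTA lower by -0.37 (adjusted p = 0.00743) beside -1.0 for clpX. However, lon is also in the heat shock list, whose medians went the same way, so lon cannot decide whether the effect was local. Gene counts do not show where in clpP the remaining reads lie.

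The second pattern is the interaction of methionine, purine, TCA, aerobic respiration and heat shock genes, lists that were not called with an estimated correlation (adjusted p = 0.436, or 0.511 for aerobic respiration). A uniformly weaker response in the deletion would make heat shock genes fall less, whereas their interaction median was -0.80. That value is part of the pattern itself, so it is no separate test. Between the strains the heat shock median was 0.59 untreated and -0.17 with DPTA. The median absolute change with DPTA over all genes was of similar size, 1.08 in WT and 1.07 in the deletion. Under 4 scalings and the removal of abundant genes the smallest list median of the interaction on its own side of 0 was 0.42. With each library left out the smallest distance from the median of all genes was 0.49. A biological difference between the strains may underlie the pattern, as a hypothesis found and examined on the same data.

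The third pattern is that flagellar genes were higher in the deletion (46 of 50 untreated and 45 with DPTA), with part of the sigma S genes (9 and 17 of 30, and 1 lower in each), a list that was not called with an estimated correlation (adjusted p = 0.667 and 0.615). The smallest of their list medians over the scalings was 0.50, which argues against scaling as the whole cause. A rise of flhDC mRNA, the flagellar master regulator, as large as that of the list is argued against in untreated cells. There the higher of the upper bounds (2 SE) of flhD and flhC was 0.40 beside a list median of 1.38. Whether a rise within that bound could move the list further was not tested, and both genes are list members. With DPTA more flhDC mRNA stays open, since the bound was 1.88. More rpoS mRNA is argued against by its values of -0.53 untreated (adjusted p = 0.0386) and -0.92 with DPTA (adjusted p = 0.000343). The untreated call of rpoS was not followed with single libraries left out. The pattern did not extend to acid resistance genes, with medians of -0.88 untreated and -0.77 with DPTA. Of these 12 genes 1 was called lower in each and 0 higher. As a list they were called lower untreated only (camera adjusted p = 0.0255, and 0.667 with an estimated correlation). In groups chosen after the result was seen, 1 of 6 curli genes was lower untreated and 4 of 5 glycogen genes with DPTA. A candidate explanation is slower breakdown of regulator proteins without the protease, which stays untested because no protein was measured.

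The 10 splits of each set of 6 libraries are too few for a share under 0.05. The real split called 2422 genes for DPTA in WT, 2445 for DPTA in the deletion, 236 for the untreated deletion and 902 for the deletion with DPTA, and the highest of the other splits called 0, 0, 0 and 3. Those other splits mix the groups compared, which puts the group difference into the spread between libraries. Their low counts follow from that and do not show what chance gives. For the interaction 1 of 100 splits, the real one, called as many as 282 genes, and the highest other called 228. Regrouping the strains puts the strain effect into the spread between libraries, so these splits do not show what chance gives for an interaction, and chance stays open by this test. The 9 other splits that keep the real strain groups under DPTA called up to 228 genes, and the rest up to 35.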

How the results depend on the processing

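The removal of 5 abundant genes was chosen only after the result was seen; the other settings were planned. No called value of a named gene or gene list changed its sign under any setting run. The side of the split with more calls did turn in each of the 5 comparisons. More genes were lower in the untreated deletion with library totals or DESeq2, and in the deletion with DPTA with library totals, upper-quartile factors or without DPTA deletion replicate 2 (384 higher, 396 lower). More interactions were positive with a fold of at least 2, DESeq2, DESeq2 size factors in edgeR, without 5 abundant genes, without any 1 untreated library or without WT DPTA replicate 3. For DPTA in WT the split of 1225 and 1197 became 1133 and 1308 with DESeq2 and turned under most settings, and for DPTA in the deletion it was 1237 and 1216 with upper-quartile factors. With library totals, upper-quartile factors and DESeq2 size factors in edgeR only the scaling differed, so the turns there follow from it. For the other settings the causes were not tested.

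With a fold of at least 2, 91 and 11 genes were higher and lower in the untreated deletion, 165 and 108 in the deletion with DPTA and 69 and 63 in the interaction, by construction of a stricter rule. The overlaps were then 654 genes higher for the DPTA response, and 38 higher and 7 lower for the deletion effect. DESeq2 called 210 genes lower in the untreated deletion and 304 with a positive interaction, and 81 shared genes lower for the deletion effect. DESeq2 size factors in edgeR gave 115 lower in the untreated deletion and 53 shared lower. Library totals gave 169 lower in the untreated deletion, 273 higher and 872 lower with DPTA, 88 positive interactions and 6 lists lower with DPTA. Upper-quartile factors gave 99 and the removal of abundant genes 98 lower in the untreated deletion.

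With an estimated correlation 5 lists were higher and 1 lower for DPTA in WT, 5 and 1 for DPTA in the deletion, 1 and 0 for the untreated deletion, 1 and 0 for the deletion with DPTA, and 0 and 0 for the interaction, for which camera with the preset correlation called 6 and 3. The calls that held were NsrR, NorR, Suf, cytochrome bd and toxin-antitoxin genes higher and methionine lower with DPTA in both strains, and flagella in both comparisons of the deletion. fry asks whether a list changed at all, whereas camera asks whether it changed more than other genes, so their counts are not alike. fry called 15 higher and 14 lower for DPTA in WT and 13 and 13 for DPTA in the deletion. It called 2 and 2 for the untreated deletion, 10 and 7 for the deletion with DPTA and 3 and 2 for the interaction. Those 3 were methionine, purine and TCA (adjusted p = 0.0415, 0.0438 and 0.0415), and the 2 heat shock and ATP-dependent proteases (0.0411 and 0.0415). Aerobic respiration had 0.0621.

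With 1 library left out, genes higher in the untreated deletion ran from 111 to 198 and lower from 34 to 79, positive interactions from 78 to 137 and negative from 66 to 140, and shared lower genes of the deletion effect from 17 (without WT DPTA replicate 1) to 38. Lists lower ran from 2 to 6 in the untreated deletion and from 2 to 5 with DPTA.

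The median of all genes moved from 0.01 to -0.12 in the untreated deletion and from -0.06 to -0.19 in the interaction with library totals, and from 0.13 to 0.02 with DESeq2 size factors, 0.23 with upper-quartile factors and 0.00 with no filter for DPTA in WT. For DPTA in the deletion it moved from 0.01 to -0.11 with no filter.

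Replicate numbers gave no clear pairing of the libraries: the median correlation of deviations between libraries of the same number was 0.01 (-0.049 to 0.203), 3 of 18 were over 0.1, and 5 of 12 libraries correlated best with their own number. Those over 0.1 all involved the untreated deletion. They were 0.11 and 0.203 with untreated WT (replicates 2 and 3) and 0.107 with WT under DPTA (replicate 3). A weak pairing there stays possible. With the replicate number as a block, 1215 and 1200 genes were called for DPTA in WT, 1167 and 1284 for DPTA in the deletion, 202 and 87 for the untreated deletion, 499 and 420 for the deletion with DPTA and 160 and 166 for the interaction. The block gave overlaps of 998, 1064, 122 and 46, and lists higher and lower of 9 and 8, 9 and 6, 3 and 4, 7 and 4, and 5 and 3. Tryptophan lost its interaction call with the block (adjusted p = 0.0505).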

Other observations

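The gene groups here were chosen only after the result was seen, and no enrichment test was made for them.

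With DPTA 6 of 7 universal stress protein genes rose in WT (median log2 2.11) and 7 of 7 in the deletion (2.83). All 5 molybdopterin synthesis genes rose in WT (1.24) and 3 in the deletion (0.54), and all 5 were lower in the deletion than in WT under DPTA (-0.98). Of 5 glycogen genes 4 rose in WT (1.10) and 3 in the deletion (0.75), and 4 were lower in the deletion under DPTA (-0.60). Of 5 biotin genes 4 fell and 1 rose with DPTA in both strains (-1.76 and -2.52), and 4 were lower in the deletion under DPTA (-1.05). Of 6 curli genes 4 fell and 1 rose in WT (-2.36), and 3 fell and 1 rose in the deletion (-1.07). csgE and csgF, which had 0 counts in the 3 deletion libraries with DPTA, are 2 of those 3: they were not tested in a fit of these 6 libraries alone, where 1 of 4 curli genes fell, 1 rose and the median was 0.20. With csgE and csgF set to 3 counts over a group where they had fewer, the medians over 12 libraries stayed at -2.36 and -1.07. Single calls lost without 1 library were csgA in WT (adjusted p = 0.103 without WT untreated replicate 2) and, in the deletion, moaC (0.0577 without DPTA replicate 2), moaD (highest 0.0864, without untreated replicates 1 or 2 or DPTA replicate 1), bioA (highest 0.074, without untreated replicates 1 or 2) and uspC (0.0678 without untreated replicate 1). moaB lost its call between the strains under DPTA without WT DPTA replicate 1 (0.0522).

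In the deletion all 3 molybdate transport genes were higher, untreated (1.39) and with DPTA (0.63). All 5 dipeptide transport genes were higher untreated (0.91) and 4 of 5 with DPTA (0.95). Untreated deletion replicate 1 mattered for these: without it dppC had adjusted p = 0.066 and dppD 0.0538, and dppB and dppF lost their call in 5 and 4 of 6 fits with 1 library left out (highest 0.198 and 0.117). Of 9 type 1 fimbrial genes 2 were lower untreated, fimA and fimB (median -1.0), and 5 with DPTA (-1.06). The untreated count depended on the method, with 5 lower by DESeq2, which tested 5 of the genes, and by limma-voom, 4 in a fit of the 6 libraries alone, 3 with library totals and 1 with no filter, while the count with DPTA was 5 by each of these. fimB lost its call with any of the 6 libraries left out (highest adjusted p = 0.17).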
